A study of Mus musculus with 28 samples.

How the data were processed

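The series profiled mouse fibroblasts, sorted cells of reprogramming cultures and iPS cells on 2 designs of 3′ expression microarrays. Per the labels, fibroblasts came from embryos of day 13.5 and were grown with doxycycline in serum and LIF medium. Cells were sorted by flow cytometry, iPS cultures were preplated to remove feeder cells, and total RNA was biotin-labelled without DNase digestion. The deposited tables hold log2 signals per probe set that the authors made with RMA, per the submitters' processing notes, which give no version and do not say which arrays were normalized together. Array medians lay between 6.835 and 6.988 in the table of 24 arrays and between 6.553 and 6.58 in the table of 4. Levels were never compared across these tables. The log2 values were used as deposited, and no raw intensities were used here.

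The larger table had 22716 probe sets, of which 18003 carried 1 gene symbol, 287 several and 4426 none in the array annotation (90 controls included). The smaller had 22690, of which 20393 carried 1, 691 several and 1606 none (64 controls included). Only probe sets with 1 symbol were used, and 0 symbols were updated. The probe set of highest mean signal stood for its gene, which left 11807 genes on the 24 arrays and 12393 on the 4. No 2 arrays held identical values.

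Groups were formed from the labels by day and sorted fraction. The labels do not state what the replicate names M2 and M3 stand for. Groups, comparisons, gene lists, the threshold of a call and the alternatives were fixed before the data were examined, apart from 1 alternative, the tests of the day 6 gap, a stricter rule for the probe-set test and a choice of fibroblast genes without the iPS arrays, which were set after seeing the data. Differences were tested with limma 3.58.1 in R 4.3.3, in a fit of all 24 arrays with 15 group means and 9 residual degrees of freedom (prior degrees of freedom 4.68). Comparisons over all days used the 18 sorted arrays of the 3 fractions with terms for day and fraction (12 residual degrees of freedom). The EpCAM comparison used its own 4 arrays (2 residual degrees of freedom). A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over all genes and at least a 2-fold difference. Groups of 1 array were tested with the spread of the replicated groups.

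The 10 genes of largest difference in each direction could be named if the arrays of the groups did not overlap (for the comparisons over all days, within no day), as could any member of a fixed list. Gene lists were written from general knowledge of the field and tested with at least 5 measured members by camera, with its preset correlation of 0.01 and again with a correlation estimated from the data. Camera p-values were adjusted over the lists of a comparison. Lists of the reprogramming factors, sex-linked genes and sorting markers had too few measured members and were not tested as groups. The factor genes are also in the cassette, and their probe sets may read its transcripts.

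The progress index of an array was the summed difference from the MEF mean over the genes called between iPS cells and MEFs, divided by the summed difference of the iPS mean. It was compared between SSEA1+ and Thy1+ arrays by exact permutation of the fraction labels within days, two-sided. The root mean square log2 difference of a comparison was taken over all genes after subtraction of the error variance. Genes shared between the day 3 comparisons were set against counts for independent lists and a simulation. In it both groups had the MEF mean and were compared with the same simulated MEF arrays.

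Each comparison was repeated with no minimum fold, without the dimmest 25% of genes, after quantile and median scaling, with the mean of all probe sets of a gene, with a trended and robust variance prior, and with the replicate name as a block. Where the arrays of a comparison allowed it, it was also repeated with only these groups in the fit, with the M2 arrays alone and leaving out each array in turn, which was not possible between lone arrays. For the comparisons over all days, the mean of within-day differences was also taken. An alternative without the day 6 Thy1+ M2 array in any fit was added after seeing the data. The 12 arrays of each comparison over all days were also split in 100 ways into 6 and 6. The pipeline was tested on simulated data with 200 changed genes. At a log2 change of 1.5 it recovered 96.5% of them between iPS cells and MEFs, 77% between the lone SSEA1+ arrays of days 9 and 12, 79% in the interaction and 85% in the EpCAM comparison, and 0 were recovered in the wrong direction. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.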

Results

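Gene expression was measured by microarray in mouse embryonic fibroblasts (MEFs), in cells sorted from them during reprogramming, and in induced pluripotent stem (iPS) cells. The fibroblasts carried a doxycycline-inducible cassette of the 4 reprogramming factors. The series held 28 arrays in 17 groups. Cells were sorted on days 3, 6, 9 and 12 of induction by Thy1, a surface protein of fibroblasts, and SSEA1, a carbohydrate surface antigen of mouse pluripotent cells. Each day gave a Thy1+ fraction, a fraction negative for both markers (here Thy1−) and an SSEA1+ fraction that was Thy1-negative. Day 12 also gave SSEA1+ cells positive for GFP, a reporter whose gene the labels do not name. MEFs and each fraction of days 3 and 6 had 2 arrays, called M2 and M3, iPS cells 3 (1-3, 1-5 and 1-6), and each fraction of days 9 and 12 had 1, from M2. On another array design, SSEA1+ cells of day 6 were split by the epithelial surface protein EpCAM, with 2 arrays per fraction. Nothing in the labels says that replicate arrays came from separate animals or cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

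The transcript of the Thy1 sorting marker followed the gates. On the log2 scale Thy1 stood at 11.79 in MEFs, at 10.86 to 11.72 in the Thy1+ fractions and at 8.18 to 9.51 in the SSEA1+ fractions. It stood at 7.01 in GFP+ cells and 6.53 in iPS cells. Fut9, a fucosyltransferase that makes the SSEA1 epitope, stood at 5.33 ± 0.11 (SD, n = 2) in day 3 SSEA1+ cells and 6.41 on the day 12 SSEA1+ array, against 3.43 to 3.46 in the Thy1+ fractions. Among replicated groups the spread was largest in day 6 Thy1+ cells, whose M2 array had a 3′ to 5′ log2 signal difference of 1.78 for Gapdh, against 0.934 on M3, and of 1.49 for Actb, against 0.791, a difference that grows with RNA degradation. The root mean square SD of that group was 0.464, against 0.241 in iPS cells, the next largest, where the 1-3 array stood apart in fibroblast genes.

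The end points of reprogramming, iPS cells and MEFs, were compared first. Regulators and markers of pluripotency were higher in iPS cells. Sox2 was higher by 8.12 (log2, SE 0.39, adjusted p = 3.56e-10), Fgf4 by 8.05 (SE 0.22, adjusted p = 2.07e-12) and Nanog by 6.82. Genes lower in iPS cells included C1qtnf3 at −7.24 (SE 0.17, adjusted p = 1.06e-12), the tendon gene Tnmd at −7.04, the proteoglycan gene Dcn at −6.42 and Thy1 at −5.27. Of 11807 genes, 3631 passed an adjusted p of 0.05 with at least a 2-fold difference, 1824 higher and 1807 lower in iPS cells. In this and later comparisons genes are named for their size of change only where every array of a group lay above every array of the other, list members are named regardless, and the count of list members adjusted over the list alone equalled the count over all genes unless it is given. Subtracting each array's median moved the median of all genes by 0.13, and the differences are relative to that shift. Xist, the RNA of the inactive X chromosome, stood at 7.57 to 7.81 on the iPS arrays and 10.78 to 11.72 on all others of the table, and the Y-linked gene Eif2s3y at 6.04 to 7.26 and 2.97 to 3.28. The Y-linked genes Kdm5d (3.93 to 4.35 and 3.69 to 4.46) and Uty (3.57 to 3.66 and 3.43 to 4.02) did not separate, so a difference in sex is not established. The 18S RNA signal was 10.642 to 11.012 on the iPS arrays and 11.998 and 12.017 on the MEF arrays, and the Actb 3′ to 5′ difference 1.041 to 1.182 and 0.808 and 0.839.

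Between iPS cells and MEFs, 29 of 30 measured pluripotency genes were higher (camera adjusted p = 1.05e-18, adjusted p = 0.0156 with an estimated correlation). Mesenchymal genes were lower in 35 of 36 cases, Postn by a log2 difference of −6.37 (camera adjusted p = 1.54e-19, adjusted p = 0.0874 with an estimated correlation). Of 28 epithelial genes 25 were higher, among them the adhesion genes Cdh1 at 7.77 and Epcam at 6.85 (camera adjusted p = 1.72e-12, adjusted p = 0.0717 with an estimated correlation). Mitotic cell cycle genes were higher in 23 of 24 cases (adjusted p = 2.62e-14, and 0.0117 as the p with an estimated correlation), and DNA replication genes in 26 of 27 (adjusted p = 2.06e-15, and 0.0349 as the p with an estimated correlation). Germline genes were higher in 13 of 15, with the meiotic gene Hormad1 at 6.12 and the germ cell helicase gene Ddx4 at 5.03 (camera adjusted p = 2.81e-07, adjusted p = 0.0117 with an estimated correlation). DNA methylation genes were higher in 8 of 10, with the cofactor gene Dnmt3l at 5.44 and the methyltransferase gene Dnmt3b at 4.50 (camera adjusted p = 0.00127, adjusted p = 0.0349 with an estimated correlation). Of 17 imprinted genes 9 were lower and 2 higher, with Dlk1 at −5.99, Igf2 at −4.79 and Meg3 at −3.93 (camera adjusted p = 0.00874, adjusted p = 0.0762 with an estimated correlation). Of 11 genes of TGF-beta signalling and its targets 9 were lower, with the receptor gene Tgfbr2 at −4.69 (camera adjusted p = 0.000218, adjusted p = 0.0908 with an estimated correlation).

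Other gene groups also separated iPS cells from MEFs. Ribosome biogenesis genes were higher in 16 of 18 cases, with Wdr12 at 2.53 (adjusted p = 5.03e-07, and adjusted p = 0.127 with an estimated correlation). Of 29 chromatin regulator genes 14 were higher, with the helicase gene Hells at 3.99 and the Polycomb gene Ezh2 at 2.84, and 1, Bmi1, was lower at −2.33 (adjusted p = 1.07e-06, and adjusted p = 0.0686 with an estimated correlation). Of 22 inflammatory genes 11 were lower, with the chemokine gene Ccl7 at −5.14, and 1, the adhesion receptor gene Icam1, was higher by 4.34 (adjusted p = 0.00832, and adjusted p = 0.31 with an estimated correlation). Of 19 immediate early and dissociation-stress genes, which respond quickly to growth signals and to the handling of cells, 8 were lower and 1 higher (adjusted p = 0.0141, and adjusted p = 0.346 with an estimated correlation), and of 29 oxidative phosphorylation genes 3 were higher (adjusted p = 0.00329, and adjusted p = 0.342 with an estimated correlation). Lists that camera did not call were p53 and senescence genes (1 higher and 6 lower of 20, adjusted p = 0.228), interferon genes (1 and 4 of 18, 0.138), glycolysis genes (3 and 0 of 16, 0.144) and genes of the 2-cell stage (1 and 0 of 5, 0.2). The same held for markers of other cell types, which were neural (6 higher and 1 lower of 19, adjusted p = 0.0793), epidermal (4 and 1 of 22, 0.138), endodermal (2 and 3 of 16, 0.856), trophoblast (6 and 0 of 16, 0.0793), muscle (3 and 3 of 22, 0.894), macrophage (3 and 3 of 20, 0.91) and endothelial (1 and 1 of 14, 0.91). Of 8 erythroid genes limma called 0 (1 higher at an unadjusted p under 0.05, camera adjusted p = 0.792), and of 12 housekeeping genes 2 were higher (adjusted p = 0.186).

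A progress index placed each array between the mean of the MEFs (0) and the mean of the iPS cells (1), over the genes higher and over the genes lower in iPS cells. On the genes higher in iPS cells, SSEA1+ cells stood at 0.397 ± 0.01 (SD, n = 2) on day 3, 0.411 ± 0.007 (SD, n = 2) on day 6, 0.513 on day 9 and 0.617 on day 12. Thy1+ cells stood at 0.274 ± 0.006 (SD, n = 2), 0.123 ± 0.031 (SD, n = 2), 0.145 and 0.087 on those days, and GFP+ cells at 0.827. Over the 12 arrays of both fractions the SSEA1+ mean was 0.458 and the Thy1+ mean 0.171, a difference of 0.287. On the genes lower in iPS cells the means were 0.515 and 0.202, a difference of 0.312. Exchanging fraction labels within days gave p = 0.0139 for each difference in an exact two-sided permutation test, the smallest p that these exchanges allow.

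**Figure D1:**
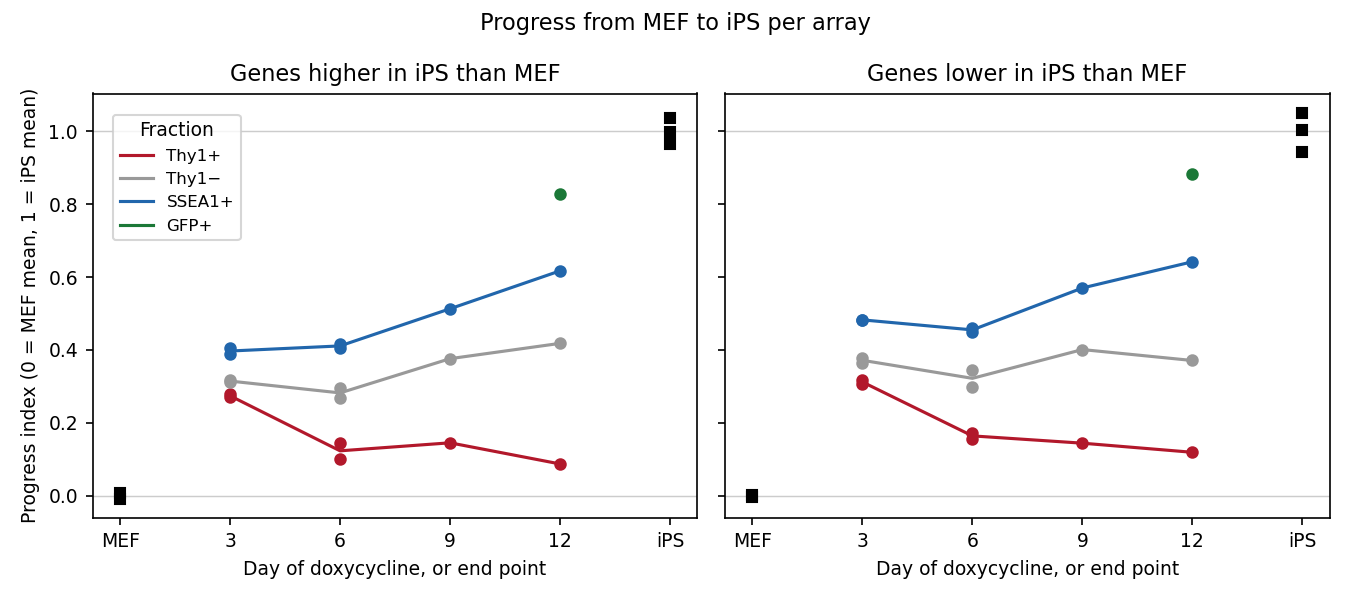
Progress index of each array (y axis, no unit, 0 is the MEF mean and 1 the iPS mean) by day of doxycycline (x axis) over genes higher (left) and lower (right) in iPS cells, with points for arrays and lines through group means. SSEA1+ arrays lie above the Thy1+ arrays of their day in both panels, and the GFP+ array lies at 0.827 and 0.883.

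The first step of the SSEA1+ course, from MEFs to day 3, lost fibroblast genes and gained cycling genes. The matrix genes Postn and Aspn changed by −7.78 (SE 0.44, adjusted p = 8.69e-09) and −7.67 (SE 0.23, adjusted p = 2.93e-11), and Agtr2, an angiotensin receptor gene, by −6.96. Podxl, which encodes a sialomucin, rose by 6.95 (SE 0.27, adjusted p = 2.67e-10), the aldehyde dehydrogenase gene Aldh3a1 by 6.85 and Perp, a desmosome-associated gene, by 6.33. In all, 1905 genes passed, 866 higher and 1039 lower. The 18S RNA signal stood at 12.017 and 11.998 on the MEF arrays and at 10.467 and 10.606 on the day 3 SSEA1+ arrays. The root mean square log2 difference, corrected for noise, was 0.901, against 0.258, 0.197 and 0.134 for the following steps to days 6, 9 and 12. With the day 6 Thy1+ M2 array left out, the values were 0.913, 0.295, 0.264 and 0.244, so the later steps differed less from each other.

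By day 3 in SSEA1+ cells every measured member of the cell cycle (24) and DNA replication (27) lists had risen, with Cdc20 at 2.78 and Mcm10 at 3.07 (camera adjusted p = 1.27e-20 and 2.66e-21). With an estimated correlation the adjusted p was 0.00573 and 0.0303. Mesenchymal genes fell in 26 of 36 cases (adjusted p = 1.71e-19, and adjusted p = 0.119 with an estimated correlation). Ribosome biogenesis genes rose in 13 of 18, led by Nolc1 at 1.88 (adjusted p = 9.89e-09, and adjusted p = 0.119 with an estimated correlation). Immediate early and dissociation-stress genes fell in 11 of 19, with Egr2 at −3.21 (adjusted p = 2.23e-06, and adjusted p = 0.119 with an estimated correlation). Of 17 imprinted genes 8 fell, Dlk1 by a log2 difference of −5.36 (adjusted p = 0.00295, and adjusted p = 0.108 with an estimated correlation). Of 28 epithelial genes 8 rose, Cdh1 by 3.20, and 1 fell, Cdh3 at −2.13 (adjusted p = 0.008, and adjusted p = 0.424 with an estimated correlation). Of 30 pluripotency genes 5 rose, with Fgf4 at 5.97 and Sall4 at 1.64 (SE 0.44, adjusted p = 0.00978), and 1 fell, Klf2 at −3.93 (list adjusted p = 0.0112, and adjusted p = 0.404 with an estimated correlation). Fgf4 averaged 10.365 over all 24 arrays, Thy1+ and Thy1− arrays included, so its high level was not particular to SSEA1+ and iPS cells. The day 3 SSEA1+ M2 array stood above M3 in Sall4 (6.78 against 5.32), Sox2 (4.96 against 3.14) and Dppa5a (8.22 against 5.53).

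Thy1+ cells of day 3, the fraction positive for the fibroblast marker, were set against MEFs in the same way. Aldh3a1 rose by 6.86 (SE 0.23, adjusted p = 1.62e-10) and Podxl by 5.69, and Agtr2 and Postn changed by −6.77 (SE 0.16, adjusted p = 6.09e-12) and −5.82. All 24 cell cycle and all 27 DNA replication genes rose (adjusted p = 1.61e-23 and 2.64e-22, and adjusted p = 0.00331 and 0.0274 with an estimated correlation). Mesenchymal genes fell in 20 of 36 cases (adjusted p = 9.24e-13, and adjusted p = 0.238 with an estimated correlation) and immediate early and dissociation-stress genes in 10 of 19 (adjusted p = 1.75e-06, and adjusted p = 0.193 with an estimated correlation). In all, 1263 genes passed, 622 higher and 641 lower, and the 18S RNA signal of the Thy1+ arrays was 10.42 and 9.986. The calls shared with SSEA1+ cells of day 3 were 543 higher and 623 lower, and 0 were opposite, where independent lists would share 45.6 and 56.4. Both comparisons used the same MEF arrays. In a simulation with both groups at the MEF mean 0 calls were shared, an outcome that its setting fixes in advance, so it decides nothing. The log2 differences correlated across genes at r = 0.943, against 0.534 in the simulation, with a covariance of 0.656 against 0.027. The simulation already holds the spread between the shared MEF arrays, so this spread does not account for the excess over it. A shift common to all MEF arrays is not in the simulation and may add to the excess. Genes are not independent replicates.

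From day 3 to day 6, fewer genes changed in SSEA1+ cells than in the first step. The tachykinin gene Tac2 rose by 4.72 (SE 0.26, adjusted p = 5.48e-07), the transcription factor gene Tfap2c by 3.25 (SE 0.22, adjusted p = 2.07e-06) and Postn, which had fallen by day 3, by 3.15 (SE 0.44, adjusted p = 0.000807). The neurofilament gene Nefl changed by −2.46 (SE 0.32, adjusted p = 0.000524) and the chemokine gene Cxcl5 by −2.06. Immediate early and dissociation-stress genes rose in 9 of 19 cases (10 adjusted over the list alone), among them Egr2 at 2.68 and Dusp6 at 1.69 (adjusted p = 2.7e-15, and adjusted p = 0.0295 with an estimated correlation). Of 17 imprinted genes 4 rose (5 adjusted over the list alone), including Meg3 at 1.46 and Cdkn1c, an inhibitor of the cell cycle, at 1.35 (adjusted p = 0.00187, and adjusted p = 0.0671 with an estimated correlation). The cell cycle list had a median of −0.42, and 0 of its 24 members passed in limma, although 18 were lower at an unadjusted p under 0.05 (camera adjusted p = 2.4e-12, adjusted p = 0.0295 with an estimated correlation). In all, 213 genes passed, 171 higher and 42 lower. Without the day 3 SSEA1+ M2 array the count was 136, and with the M2 arrays alone 103.

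Day 9 SSEA1+ cells were compared with those of day 6, 1 array against 2. The pluripotency regulator genes Nanog and Nr0b1 rose by 2.86 (SE 0.49, adjusted p = 0.0123) and 2.31 (SE 0.18, adjusted p = 2.46e-05), Sall4 by 2.57, Pou5f1 by 1.43, and the epithelial genes Epcam and Esrp1 by 2.19 and 2.17. Inflammatory genes fell, with Ptgs2 at −2.67 (SE 0.57, adjusted p = 0.0492), Il6 at −2.58 and Cxcl1 at −2.31. Pluripotency genes rose in 6 of 30 cases, and 1, Tbx3, fell by 1.20 (list adjusted p = 1.31e-05, and adjusted p = 0.222 with an estimated correlation). Epithelial genes rose in 5 of 28 (9 adjusted over the list alone, adjusted p = 3.55e-16, and adjusted p = 0.113 with an estimated correlation), and inflammatory genes fell in 4 of 22 (6 adjusted over the list alone, adjusted p = 2.8e-11, and adjusted p = 0.0951 with an estimated correlation). In all, 76 genes passed, 39 higher and 37 lower. In a fit of only these groups every gene with at least a 2-fold difference passed, so its count is only a count of folds. The count was 19 without the day 6 SSEA1+ M2 array, 172 in a fit of only these groups and 146 when the day 6 Thy1+ M2 array was left out of the fit, where epithelial genes rose in 9 cases and inflammatory genes fell in 6, and 3 mesenchymal genes fell against 0 with all arrays (11 lower at an unadjusted p under 0.05 in limma).

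Between days 9 and 12, pluripotency genes rose in SSEA1+ cells, 1 array against 1. Dppa5a rose by 5.46 (SE 0.90, adjusted p = 0.0082), Sox2 by 5.07 (SE 0.60, adjusted p = 0.000795), the RNA-binding protein gene Lin28a by 4.85 (SE 0.24, adjusted p = 2.04e-07) and the homeobox gene Otx2 by 4.33. Of 30 pluripotency genes 9 rose (17 adjusted over the list alone, adjusted p = 9.92e-39, and adjusted p = 0.00335 with an estimated correlation). Of 28 epithelial genes 4 rose (8 adjusted over the list alone), including Cldn7 and Esrp1 at 2.67 each (adjusted p = 8.2e-21, and adjusted p = 0.0385 with an estimated correlation). In all, 68 genes passed, 60 higher and 8 lower, the mesenchymal factor gene Prrx1 among the latter at −1.61. The lone arrays are assumed to vary like the replicated groups. Their 18S RNA signal was 10.819 on day 9 and 11.512 on day 12, and their Actb 3′ to 5′ difference 0.836 and 1.02. Without the day 6 Thy1+ M2 array in the fit 113 genes passed, 7 of them epithelial list members, and without the dimmest 25% of genes 42.

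GFP+ cells of day 12 were compared with the remaining SSEA1+ cells of that day, 1 array against 1. Pluripotency genes were higher in GFP+ cells, and the largest differences included Lefty1 at 3.15 (SE 0.33, adjusted p = 3.27e-05), Dnmt3l at 3.14, Dppa3 at 3.08 and the homeobox gene Hesx1 at 3.58 (SE 0.20, adjusted p = 2.42e-07). Ehf, an epithelial transcription factor gene, was lower at −5.46 (SE 0.36, adjusted p = 7.83e-07), as were the Hox genes Hoxd9 at −4.02, Hoxa10 at −3.99 and Hoxd10 at −3.87. Pluripotency genes were higher in 18 of 30 cases (19 adjusted over the list alone, adjusted p = 2.56e-20, and adjusted p = 0.0169 with an estimated correlation) and germline genes in 8 of 15 (9 adjusted over the list alone), with Hormad1 at 2.97 (adjusted p = 8.78e-09, and adjusted p = 0.00867 with an estimated correlation). Mesenchymal genes were lower in 10 of 36 cases (15 adjusted over the list alone, adjusted p = 8.98e-09, and adjusted p = 0.318 with an estimated correlation). In all, 848 genes passed, 290 higher and 558 lower, and the split was 389 and 478 after each array's median was subtracted.

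The last step set iPS cells, 3 arrays, against the GFP+ array. The noise-corrected root mean square log2 difference was 0.547, against 0.542 between GFP+ and SSEA1+ cells of day 12. The 18S RNA signal was 11.685 on the GFP+ array and 10.642 to 11.012 on the iPS arrays. The Gapdh 3′ to 5′ difference was 0.726 and 0.579 to 0.664, and that of Actb 0.987 and 1.041 to 1.182. Ddx4 was higher in iPS cells by 3.75 (SE 0.23, adjusted p = 3.81e-07), the heat shock factor gene Hsf2 by 3.94 (SE 0.14, adjusted p = 1.36e-09) and Ptgs2 by 4.13. The imprinted RNA genes Meg3 and Rian were lower at −3.44 (SE 0.36, adjusted p = 1.93e-05) and −2.41, and Tac2 at −3.47. Germline genes were higher in 7 of 15 cases and 1, Rhox5, was lower at −1.14 (list adjusted p = 0.000291, and adjusted p = 0.0974 with an estimated correlation). The median of that list was 0.888, and −0.161 once the dimmest 25% of genes were left out (camera adjusted p = 0.921). That filter goes by the mean over all 24 arrays, so it also drops members high on few arrays, such as Ddx4 and Hormad1 (percentiles 12.7 and 11.4). The turned median therefore does not speak to those members. Of 17 imprinted genes 6 were lower and 1, Phlda2, higher (adjusted p = 0.00433, and adjusted p = 0.129 with an estimated correlation). Pluripotency genes were higher in 4 of 30 cases (5 adjusted over the list alone), with Klf5 at 2.06 and Klf2 at 1.60 (adjusted p = 0.000291, and adjusted p = 0.48 with an estimated correlation). In all, 854 genes passed, 471 higher and 383 lower in iPS cells. Fibroblast genes stood higher on the iPS 1-3 array than on the 1-5 and 1-6 arrays, as Ptgs2 did at 9.29 against 8.02 and 7.94. Ptgs2 stood at 4.29 on the GFP+ array and at 11.13 and 11.27 on the MEF arrays.

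**Figure D2:**
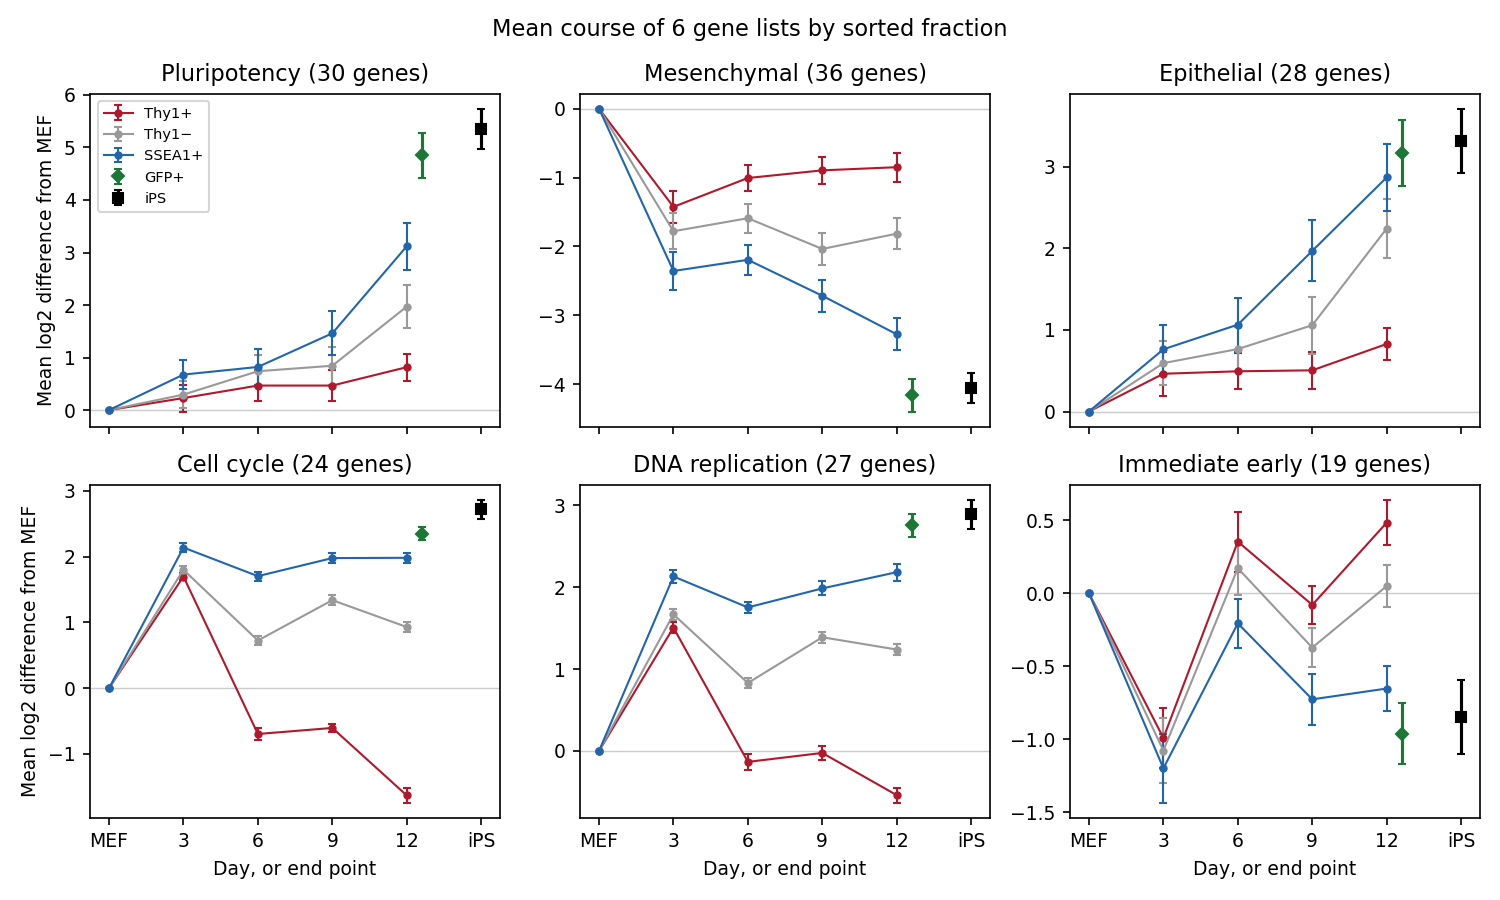
Mean log2 difference from MEFs (y axis) over the measured members of 6 gene lists by day of doxycycline (x axis), with bars for the standard error over genes, lines for the 3 sorted fractions, a diamond beside day 12 for the GFP+ array and a square for iPS cells. Cell cycle genes of Thy1+ cells stood at 1.70 on day 3 and −1.63 on day 12, while those of SSEA1+ cells stood at 2.14 and 1.98.

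Thy1+ cells of day 12, sorted for the fibroblast marker late in induction, were compared with Thy1+ cells of day 3, 1 array against 2. All 24 cell cycle genes fell, with the kinase gene Bub1 at −4.25 (SE 0.19, adjusted p = 6.34e-09), Ccnb2 at −4.14 and Mki67 at −3.76 (list adjusted p = 1.42e-42, and adjusted p = 0.000311 with an estimated correlation). DNA replication genes fell in 25 of 27 cases (26 adjusted over the list alone), with Mcm5 at −3.63 (adjusted p = 8.4e-31, and adjusted p = 0.0092 with an estimated correlation). Egfl6 rose by 5.86 (SE 0.27, adjusted p = 6.34e-09), Igfbp5, an IGF-binding protein gene, by 5.55 and the elastin gene Eln by 4.97. Of 36 mesenchymal genes 7 rose, with Postn at 3.06 and Dcn at 3.02, and 3 fell, with S100a4 at −2.74 (adjusted p = 0.0049, and adjusted p = 0.58 with an estimated correlation). Immediate early and dissociation-stress genes rose in 13 of 19, with Fosb at 3.39 (adjusted p = 2.91e-09, and adjusted p = 0.0752 with an estimated correlation). In all, 1136 genes passed, 591 higher and 545 lower. The 18S RNA signal was 12.058 on the day 12 array against 10.42 and 9.986 on those of day 3, and the Gapdh 3′ to 5′ difference 1.11 against 0.732 and 0.738.

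Within each day, SSEA1+ cells were compared with Thy1+ cells to follow how the fractions part. On day 3, 204 genes passed, 37 higher and 167 lower in SSEA1+ cells. The adhesion genes Mpzl2 and Cadm1 were higher by 3.16 (SE 0.28, adjusted p = 9e-05) and 2.51, and Fut9 by 1.90. The cytokine genes Il6 and Cxcl12 were lower at −2.14 (SE 0.39, adjusted p = 0.00703) and −2.06. Mesenchymal genes were lower in 14 of 36 cases (15 adjusted over the list alone, adjusted p = 2.23e-26, and adjusted p = 0.0982 with an estimated correlation) and inflammatory genes in 6 of 22 (7 adjusted over the list alone, adjusted p = 1.76e-10, and adjusted p = 0.0412 with an estimated correlation). Of 24 cell cycle and 27 DNA replication genes limma called 0 on day 3, with 15 and 23 higher at an unadjusted p under 0.05 (camera adjusted p = 5.83e-12 and 2.01e-20, adjusted p = 0.0362 with an estimated correlation for both). Leaving out any single array of these 4 left 94 to 116 calls: 94 without Thy1+ M3, 107 without Thy1+ M2, 103 without SSEA1+ M2 and 116 without SSEA1+ M3. With the M2 arrays alone the count was 53.

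On day 6 the SSEA1+ to Thy1+ comparison called 1433 genes, 695 higher and 738 lower. Cell cycle genes were higher in 23 of 24 cases, with Cenpe at 3.48 (SE 0.26, adjusted p = 6.73e-07) and Mki67 at 3.17 (list adjusted p = 1.5e-30, and adjusted p = 0.00119 with an estimated correlation). DNA replication genes were higher in 26 of 27 (adjusted p = 3.07e-26, and adjusted p = 0.016 with an estimated correlation), and mesenchymal genes lower in 22 of 36, with Loxl1 at −2.54 (adjusted p = 1.38e-12, and adjusted p = 0.2 with an estimated correlation). Cdh1 was higher by 3.25 and the innate immune receptor gene Tlr4 lower at −3.04. The Thy1+ M2 array with the high Gapdh and Actb 3′ to 5′ differences belongs to this comparison. Without it 960 genes passed, 24 cell cycle and 25 DNA replication genes among them. Without the Thy1+ M3 array 2558 passed, with the M2 arrays alone 2465, and in a fit of only these groups 480.

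The later days widened the distance. On day 9, 1537 genes passed, 615 higher and 922 lower, and on day 12, 2179, with 1058 higher and 1121 lower, 1 array against 1 each. The noise-corrected root mean square log2 difference was 0.25, 0.641, 0.725 and 0.933 on days 3, 6, 9 and 12. With the day 6 Thy1+ M2 array left out, the values were 0.288, 0.548, 0.754 and 0.955. On day 9 the secreted protein gene Fetub was higher by 4.33 (SE 0.44, adjusted p = 1.22e-05) and Eras, an embryonic stem cell Ras gene, by 3.84, and all 24 cell cycle genes were higher (adjusted p = 1.22e-29, and adjusted p = 0.00135 with an estimated correlation). On day 12 Eras was higher by 4.81 (SE 0.37, adjusted p = 5.41e-07) and Nr0b1 by 4.75, and Aspn lower at −4.92. The Gapdh 3′ to 5′ difference was 1.11 on the day 12 Thy1+ array and 0.829 on the SSEA1+ array (0.98 and 0.818 on day 9), and the 18S RNA signal 12.058 and 11.512 (10.169 and 10.819). Pluripotency genes were then higher in 23 of 30 cases (adjusted p = 1.46e-12, and adjusted p = 0.0563 with an estimated correlation). Epithelial genes were higher in 18 of 28 (adjusted p = 2.01e-12, and adjusted p = 0.0637 with an estimated correlation), mesenchymal genes lower in 31 of 36 (32 adjusted over the list alone, adjusted p = 7.97e-21, and adjusted p = 0.072 with an estimated correlation) and inflammatory genes lower in 14 of 22 (15 adjusted over the list alone, adjusted p = 1.77e-08, and adjusted p = 0.0563 with an estimated correlation).

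The change of the SSEA1+ to Thy1+ difference from day 3 to day 6 was tested as an interaction. The difference widened in cell cycle genes. Pclaf, a PCNA-binding factor gene, changed by 3.05 (SE 0.32, adjusted p = 0.00014), Cenpe by 2.97 and Mki67 by 2.79, and 23 of 24 members passed (list adjusted p = 5.4e-45, and adjusted p = 0.000248 with an estimated correlation). DNA replication genes passed in 20 of 27 cases (22 adjusted over the list alone, adjusted p = 3.26e-29, and adjusted p = 0.0111 with an estimated correlation). Eln and Mfap4, genes of elastic fibres, changed the other way, by −2.68 (SE 0.31, adjusted p = 0.000238) and −2.64. In all, 220 genes passed, 162 of them upward. Leaving out the day 6 Thy1+ M2 array gave 235, with 17 DNA replication genes, and leaving out its replicate M3 gave 1990. The count was 132 without Thy1+ M2 or M3 of day 3 or SSEA1+ M2 of day 6, 136 and 135 without SSEA1+ M2 and M3 of day 3, and 82 in a fit of only these groups.

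Over all 4 days together, with day and fraction as additive terms and 6 arrays per fraction, SSEA1+ cells differed from Thy1+ cells in 1012 genes, 413 higher and 599 lower. Mpzl2 was higher by 3.77 (SE 0.35, adjusted p = 3.74e-06) and Bex4 by 3.28, and Aspn and C1qtnf3 lower at −2.83 (SE 0.30, adjusted p = 8.27e-06) and −2.79. Mesenchymal genes were lower in 26 of 36 cases (adjusted p = 4.86e-20, and adjusted p = 0.21 with an estimated correlation) and inflammatory genes in 13 of 22 (adjusted p = 8.49e-08, and adjusted p = 0.21 with an estimated correlation). Cell cycle genes were higher in 23 of 24 over the days together, though 0 passed on day 3 alone (adjusted p = 1.17e-12, and adjusted p = 0.211 with an estimated correlation), and pluripotency genes in 9 of 30 (10 adjusted over the list alone, adjusted p = 0.000142, and adjusted p = 0.406 with an estimated correlation).

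On the progress index Thy1− cells lay between the other fractions on each day, at 0.418 on day 12 over the genes higher in iPS cells. Against Thy1+ cells they differed in 225 genes, 136 higher and 89 lower, with Mpzl2 higher by 2.62 (SE 0.35, adjusted p = 0.00294), Cdh1 by 1.91 and Thy1 lower at −1.76 (SE 0.21, adjusted p = 0.00294). Cell cycle genes were higher in 19 of 24 cases (adjusted p = 3.28e-15, and adjusted p = 0.23 with an estimated correlation). Against Thy1− cells, SSEA1+ cells differed in 106 genes, 10 higher and 96 lower, with Fut9 higher by 1.92 (SE 0.17, adjusted p = 5.97e-05), Nr0b1 by 1.69 and Nanog by 1.52, and the aldehyde oxidase gene Aox3 lower at −1.92. After each array's median was subtracted the split was 17 and 83. Mesenchymal genes were lower in 10 of 36 (11 adjusted over the list alone, adjusted p = 5.22e-24, and adjusted p = 0.206 with an estimated correlation). Both counts hung on single arrays. The Thy1− to Thy1+ count was 63 and 73 without the Thy1+ arrays of days 9 and 12, 73 and 107 without the Thy1− arrays of those days, 130 without Thy1− M3 of day 6 and 349 without Thy1+ M2 of day 3, and the SSEA1+ to Thy1− count was 35 and 27 without the SSEA1+ arrays of days 9 and 12, 70 without the Thy1− array of day 12, 54 without Thy1− M2 of day 6 and 59 without Thy1− M3 of day 3.

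Genes off the line between the end points were counted as those that differed from both MEFs and iPS cells in 1 direction. In day 6 SSEA1+ cells 456 genes did so, 299 higher than both and 157 lower than both. Such genes were not particular to that fraction, with 673 in day 6 Thy1+ cells, 422 in day 6 Thy1− cells and 303 to 515 in the other sorted groups. Tac2 stood 7.75 (SE 0.26, adjusted p = 9.17e-11) above MEFs and 6.06 above iPS cells, Ehf 5.86 and 6.13, Aldh3a1 6.86 and 5.76, and the thyroid hormone-binding protein gene Crym 6.44 and 4.92. Lower than both were the transcription factor gene Klf2, at −3.81 and −4.41 (SE 0.27 and 0.25), Bcar3 at −3.22 and −4.58 and the kinase gene Sgk1 at −3.15 and −3.58. Ehf stood at 9.07 in day 12 SSEA1+ cells, 3.61 in GFP+ cells and 3.12 in iPS cells.

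The EpCAM split of day 6 SSEA1+ cells was fitted on its own 4 arrays, whose levels are not comparable with those of the other table. On these arrays the Y-linked genes stood above Xist, the reverse of the time course, so the cells may not come from the same animals. EpCAM+ cells had higher Nanog, by 3.42 (SE 0.14, adjusted p = 0.00116), Epcam itself by 2.94 (SE 0.13, adjusted p = 0.00116), Eras by 2.81, Sox2 by 2.40 and the keratin gene Krt8 by 2.36. Lower were Cdh11, a mesenchymal cadherin gene, at −1.50 (SE 0.13, adjusted p = 0.00772), Ecrg4 at −1.72 and the collagen gene Col3a1 at −1.36. Of 32 pluripotency genes 10 were higher (adjusted p = 3.84e-15, and adjusted p = 0.308 with an estimated correlation), as were 10 of 29 epithelial genes (11 adjusted over the list alone, adjusted p = 7.74e-17, and adjusted p = 0.308 with an estimated correlation), and 6 of 41 mesenchymal genes were lower (7 adjusted over the list alone, adjusted p = 5.67e-09, and adjusted p = 0.4 with an estimated correlation). Of 1776 genes higher in iPS cells than MEFs 42 were higher in EpCAM+ cells (44 adjusted over the list alone, adjusted p = 1.63e-16), and of 1774 lower in iPS cells 28 were lower and 3 higher (adjusted p = 4.3e-17). With an estimated correlation the adjusted p was 0.308 for both lists, which were drawn from the other arrays of this series and are not independent evidence of direction. In all, 93 genes passed, 60 higher and 33 lower. The EpCAM− arrays differed from each other in the 3′ to 5′ difference of Gapdh (0.624 and 0.309) and Actb (0.707 and 0.486) and in 18S RNA signal (12.301 and 11.008). Without EpCAM− array 1 or 2 limma called 0 genes (114 and 94 at least 2-fold at an unadjusted p under 0.05), and without EpCAM+ array 1 or 2 it called 6 and 4.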

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

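The tests of the day 6 gap in cell cycle and DNA replication genes were chosen only after the result was seen. The choice of fibroblast genes without the iPS arrays was also made after seeing the data. The rule for the comparison of probe sets was made stricter after its value was seen, so that its whole interval had to stay within 10 points.

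A difference between groups drew attention to 220 genes whose SSEA1+ to Thy1+ difference changed from day 3 to day 6. The largest upward changes were in Pclaf (3.05), Cenpe (2.97), Ttk (2.80), Mki67 (2.79), Zwilch (2.76), Cep55 (2.73), Aspm (2.70), Bub1 (2.61), Shcbp1 (2.56) and Ska1 (2.55). The largest downward changes were in Eln (−2.68), Mfap4 (−2.64), Aqp4 (−2.43), Rflnb (−2.24), Igfbp5 (−2.13), Tlr4 (−2.05), Sorcs2 (−2.03), Prkg1 (−1.91), Fxyd1 (−1.89) and Sod3 (−1.88). A signal in data not reported on was the 1199 probe sets with no single gene symbol that were called between iPS cells and MEFs.

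The gap in cell cycle and DNA replication genes could come from the day 6 Thy1+ M2 array with its signs of lower RNA quality. Without that array the median change of the gap over the 51 list members kept 102.1% of its value (1.576 ± 0.562 SD over genes, against 1.544 ± 0.643), which argues against that array as the cause. If the Thy1+ cells themselves fell in these genes after day 3, the lone Thy1+ arrays of days 9 and 12, which do not enter the interaction, should lie below the day 3 Thy1+ mean, and 100% of the members did on both. This fits a fall in Thy1+ cells, as a hypothesis found and tested on the same arrays. The day 12 part was already known from the comparison of Thy1+ cells of days 12 and 3. On days 3 and 6 themselves the mean of cell cycle genes against MEFs was 1.70 and −0.70 in Thy1+ cells, and 2.14 and 1.70 in SSEA1+ cells. For DNA replication genes it was 1.51 and −0.13, and 2.13 and 1.75. The wider gap thus lay mainly in the Thy1+ fraction. Slower division of the cells and a change in which cells the Thy1+ gate holds were not tested apart.

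Between iPS cells and both GFP+ cells and MEFs, 458 genes differed in 1 direction. If single probe sets that read differently on the iPS arrays were the source, other probe sets of these genes should agree less often than those of genes already changed in GFP+ cells, and they agreed in 63.5% of the 159 such genes with other probe sets against 67.8% of 1107, 4.2 points lower (interval −3.7 to 12.2, Fisher's exact test p = 0.32), which leaves this open. After quantile normalization 94.1% of the genes kept both calls. RMA values are already close to equal quantiles, and this step moved the median of iPS against GFP+ cells by only 0.053. It could hardly have failed, so an intensity-dependent difference in normalization stays open. The iPS cultures were preplated and the GFP+ cells were sorted, so culture, sorting and any array batch are confounded with the group. The origin or sex of the cells may be confounded as well, but the sex-linked genes disagree. Xist stood at 7.57 to 7.81 in iPS cells and 10.78 to 11.72 elsewhere, and Eif2s3y at 6.04 to 7.26 and 2.97 to 3.28. The Y-linked genes Kdm5d (3.93 to 4.35 and 3.69 to 4.46) and Uty (3.57 to 3.66 and 3.43 to 4.02) did not separate. A difference in sex is therefore not established, and the source of these differences was not tested.

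Fibroblast genes stood higher on the iPS 1-3 array than on the 1-5 and 1-6 arrays, first noticed in Ptgs2, Cav1, Lox and Col1a1. On every iPS array these genes also stood above the GFP+ array, Cav1 at 8.06 to 9.42 against 4.91 and Ptgs2 at 7.94 to 9.29 against 4.29. Dcn went the other way, at 4.93 to 6.15 against 7.7. Fibroblasts left in the 1-3 culture, such as feeder cells, could be a source of its excess, although the protocol preplated the cells to remove them. Of 100 genes high in MEFs and low in GFP+ cells and on the 1-5 and 1-6 arrays, 89% were higher on 1-3 than on both others, but choosing genes low on those arrays favours this outcome, so the value decides nothing. Of 100 genes high in MEFs and low in GFP+ cells, chosen without the iPS arrays, 81% were highest on 1-3, 16% on 1-5 and 3% on 1-6, against 35.9%, 38.8% and 25.3% of all genes. Fibroblast cells and a partial fibroblast programme in this culture cannot be told apart, since there is only 1 array of it.

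Whether an arbitrary division of the arrays would give as many calls was tested for the comparisons over all days, with 100 splits into 6 and 6 each, the real one included. For SSEA1+ against Thy1+ cells 1 split, the real one with 1012 calls, reached that count, and the highest other count was 715, in a split that exchanged 1 array. For Thy1− against Thy1+ and for SSEA1+ against Thy1− cells again 1 split, the real one, reached its count, and the highest other count was 0. No call was made in 95, 99 and 99 of the other splits, in the order of the 3 comparisons. Those splits mix the real fractions, so any difference between the fractions enters their spread and lowers their counts. The values argue against a wholly arbitrary division in all 3. They do not bear on the size of the counts, which for Thy1− cells hung on single arrays.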

How the results depend on the processing

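The alternative without the day 6 Thy1+ M2 array was chosen only after the data were seen. Over all alternatives 2254 list results kept their side of the threshold, 50 lost a call, 43 gained a call and 2 turned direction. Genes were followed only where they were among the largest calls of the main fit, which favours keeping a call and allows no gain. Of the results for these named genes 4432 kept their side and 299 lost a call, and 204 counts of calls stayed within 1.5 times while 54 did not. The latter are covered below. Ranges on leaving out 1 array are given for every result that has them, also where it stayed within 1.5 times. The cause of a move was not tested unless the setting itself lowers the number of arrays or genes. With no minimum fold, which admits small differences by construction, the counts were 6624 (iPS cells against MEFs), 4057 and 2807 (day 3 SSEA1+ and Thy1+ against MEFs), 448 (SSEA1+ day 6 against 3), 2293 (iPS against GFP+ cells), 2241 (Thy1+ day 12 against 3), 464, 3568, 2380 and 3274 (SSEA1+ against Thy1+ on days 3, 6, 9 and 12), 1192 (off the line in day 6 SSEA1+ cells), 4656, 1434 and 702 (over all days, in the order of the report) and 340 (EpCAM). With only the M2 arrays, 1 against 1, they were 103 (SSEA1+ day 6 against 3), 53 and 2465 (SSEA1+ against Thy1+ on days 3 and 6). With only the compared groups in the fit they were 172 (SSEA1+ day 9 against 6), 480 (SSEA1+ against Thy1+ on day 6) and 82 (interaction). Without the dimmest 25% of genes 42 genes passed between days 9 and 12 of SSEA1+ cells. Means of within-day differences gave 381 (Thy1− against Thy1+) and 193 (SSEA1+ against Thy1−). Without the day 6 Thy1+ M2 array the SSEA1+ counts were 146 (day 9 against 6) and 113 (day 12 against 9). Leaving out 1 array of the comparison gave 3568 to 3747 (iPS cells against MEFs), 1818 to 1888 and 1189 to 1205 (day 3 SSEA1+ and Thy1+ against MEFs), 136 to 148 (SSEA1+ day 6 against 3), 19 to 61 (day 9 against 6), 871 to 942 (iPS against GFP+), 992 to 1009 (Thy1+ day 12 against 3), 94 to 116 and 960 to 2558 (SSEA1+ against Thy1+ on days 3 and 6), 132 to 1990 (interaction), 424 to 458 (off the line), 836 to 1173, 63 to 349 and 27 to 149 (over all days) and 0 to 6 (EpCAM). The progress difference ranged from 0.255 to 0.308 on genes higher and from 0.287 to 0.335 on genes lower in iPS cells. Without the dimmest 25% of genes, which leaves fewer members, the median of germline genes between iPS and GFP+ cells was −0.161 and that of neural genes between days 12 and 3 of Thy1+ cells −0.951 (0.176 with all genes). That filter goes by the mean over all arrays of the table, so it also drops genes high on few arrays, such as the germline genes Ddx4 and Hormad1. Low signal limits genes near the background of the arrays, where a fold is compressed.

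With the replicate name as a replicate block, 3631 genes passed between iPS cells and MEFs, 1904 between day 3 SSEA1+ cells and MEFs, 1437 between SSEA1+ and Thy1+ cells on day 6, 204 in the interaction, 1012 over all days between SSEA1+ and Thy1+ cells and 96 in the EpCAM comparison. The block moved no count of calls by more than 1.5 times. Residuals of arrays with a shared name correlated above 0.1 in 5 of 21 pairs of groups (−0.207 to 0.214), so the name was not taken as a pairing, and what arrays of a name share stays open. Fraction labels were also exchanged only between arrays of the same day and replicate name. The progress differences then had p = 0.0312 in an exact permutation test, the smallest p that these exchanges allow.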

Other observations

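In the separately normalized EpCAM table Xist stood at 4.58 and 4.56 in EpCAM− and EpCAM+ cells, Eif2s3y at 9.35 and 9.55, Kdm5d at 7.65 and 7.69 and Uty at 7.17 and 7.20. On the MEF and sorted arrays of the other table the order was reversed. There Xist stood at 10.78 to 11.72, Eif2s3y at 2.97 to 3.28, Kdm5d at 3.69 to 4.46 and Uty at 3.43 to 4.02. The EpCAM cells may therefore come from animals of another sex than the time course, which was not tested.

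Pluripotency genes differed between some replicates. In day 6 Thy1− cells Dppa5a stood at 7.42 on M3 and 5.62 on M2, Sall4 at 6.74 and 5.32, and Nanog at 5.69 and 4.41. In day 3 SSEA1+ cells Nanog stood at 5.97 on M2 and 4.74 on M3, and Dppa2 at 4.78 and 3.24.

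Krtdap, a gene of keratinocyte differentiation, stood at 4.72 in MEFs, 11.80 in day 12 SSEA1+ cells, 9.18 in GFP+ cells and 5.79 in iPS cells. Tac2 stood at 3.53, 11.87, 8.70 and 5.23 in that order. Hoxd10 stood at 8.38 in MEFs, 8.15 in day 12 SSEA1+ cells, 4.28 in GFP+ cells and 4.23 in iPS cells.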
